A study of Sus scrofa with 6 samples.

How the data were processed

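RNA from fat, liver and muscle of Berkshire and Korean native pigs (Sus scrofa) was sequenced in 6 libraries, 1 for each combination of 2 breeds and 3 tissues. The labels' protocols state that frozen tissue was extracted with Trizol and that 1 µg of total RNA went into each Illumina TruSeq RNA library. Reads were aligned with TopHat to the Sscrofa10.2 build and counted per gene with HTSeq 0.5.3p3, per the submitters' processing notes. The deposited values are raw counts of reads per Ensembl gene ID. The strand setting, the counting mode and the annotation release are not given in the sources used here, so reads of overlapping or antisense genes cannot be told apart.

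Each file lists 25322 gene IDs and 5 closing entries that name no gene. These entries were left out of library sizes and tests. Reads outside annotated genes made up 45.9% to 52.5% of the entries of a library, and reads without a unique alignment made up 14.1% to 20.8%. A library kept between 5897407 and 7912093 counts on genes. A count of 0 in 1 library therefore allows a level of up to 0.294 to 0.692 TMM-scaled CPM, the value of 3 counts in that library. Intervals and floors cover counting error only. Symbols were taken from the supplied table of gene names, which matched 11804 of the 25322 IDs (46.6%), and these carried between 77.8% and 82.3% of the counts of a library. Only genes with a symbol are named, apart from 4 IDs.

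Tissues were compared by an additive model of tissue and breed over all 6 libraries, with edgeR 4.0.16 in R 4.3.3. TMM factors were used, and genes were kept by filterByExpr on that design, which left 13810 genes. The quasi-likelihood test was two-sided, with the Benjamini-Hochberg adjusted p held under 0.05. Each SE printed is the size of the log2 value over the square root of the F statistic of that test. It is not an SE given by the fit. The model has 2 residual degrees of freedom and takes the departure of a breed difference between tissues as its spread. The common dispersion corresponded to a biological coefficient of variation of 29.5%. A gene was called enriched in a tissue when it passed against both other tissues with a log2 fold of at least 2. The breed coefficient of the same model gave the comparison of breeds over tissues. The series title speaks of 3 of each breed without saying whether animals or tissue samples are meant, and the labels do not say whether the libraries of a breed come from 1 animal or from several, so a p-value measures only the spread among these libraries.

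Within a tissue each breed has 1 library, so no test was made and no p-value is given. Genes with at least 10 CPM in 1 of the 2 libraries and a ratio of at least 4-fold were counted, with a prior count of 2. Genes at least 2-fold apart in the same direction in all 3 tissues were counted among genes with at least 5 CPM in 1 library of each tissue. Turning the sign of 1 tissue gave the count of genes that moved in that tissue against the other 2. Agreement itself lowers such counts, so they are not the counts expected without agreement. A set of 38 gene lists was fixed before the data were examined, and 37 kept at least 5 tested members. Camera from limma 3.58.1 tested them with an inter-gene correlation of 0.01 and again with an estimated correlation. With an estimated correlation, camera also draws its p from the 2 residual degrees of freedom of the model. The hepatocyte markers in liver against fat had an estimated correlation of -0.03, below 0.01, yet the camera p went from 1.1e-21 to 0.0091. A call lost in this way is therefore not by itself a sign of correlated genes. Within a tissue, a list median was placed among 10000 random lists of equal size matched on mean expression. Such a percentile describes these libraries and is no test.

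Genes named in the text follow a rule fixed at that time. For tissues these are the 10 enriched genes of highest mean CPM in each tissue and up to 4 abundant members of a list. For breeds over tissues they are the 5 genes of smallest p in each direction, because fewer than 5 genes with a symbol passed. Within a tissue they are the 10 genes of largest ratio in each direction and, for a list outside the 2.5th to 97.5th percentile, its 4 members of largest ratio in that direction with at least 5 CPM in 1 library. Not every gene that the rule selects is printed. For all tissues together they are the 6 genes in each direction with the largest smallest ratio. ALB, APOA1, ADIPOQ, PLIN1, ACTA1 and CKM were to be given as checks of the labels. ADIPOQ and CKM matched no ID, and the ID named APOA1 reached 1.20 CPM in Berkshire liver and 1.33 CPM in Korean native liver, too few to be tested.

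The procedure was tested on simulated counts with known changes. For liver against fat, over 13240 genes, it recovered 3 of 57 genes changed 2-fold, 44 of 70 changed 4-fold and 58 of 65 changed 8-fold, and it called 20 unchanged genes. For the breed difference, over 13200 genes, it recovered 2 of 65 changed 2-fold, 47 of 61 changed 4-fold and 63 of 66 changed 8-fold, and it called 9 unchanged genes. In both comparisons unchanged genes made up a larger share of the calls than the adjusted p limit of 0.05. The simulated tissues differed only by the known changes, so the scaling between unlike tissues was not tested. Alternatives were other scalings (DESeq2 1.42.0 median-of-ratios factors, or total counts), DESeq2 and limma-voom tests, other filters, models without breed or tissue, and the omission of each library. Further calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.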

Results

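Messenger RNA levels were measured by RNA sequencing in fat, liver and muscle of Berkshire and of Korean native pigs. Each breed and tissue was represented by 1 library, giving 6 libraries in all. Levels below are TMM-scaled CPM, and tissue means are given with the SD over the libraries of both breeds (n = 2). Values within a breed and tissue have no replicate.

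The first comparison asked which genes distinguish the 3 tissues. Liver was marked by plasma proteins. ALB (albumin, ENSSSCG00000008948) stood at 194695 ± 25746 CPM in liver against 25.8 ± 7.35 in fat and 51.6 ± 1.34 in muscle. TF (transferrin), HRG (histidine-rich glycoprotein), CP (ceruloplasmin), C3 (complement component), A2M and PLG (plasminogen) were also enriched, from 6321 ± 1023 CPM for PLG to 15826 ± 394 CPM for TF in liver. CAT (catalase), APOE (apolipoprotein E) and FN1 (fibronectin) were enriched too, with 1342 ± 165, 973 ± 108 and 1886 ± 1082 CPM in fat. The log2 difference between liver and fat ranged from 2.41 ± 0.65 (SE) for FN1 to 13.31 ± 0.70 for HRG, with edgeR adjusted p of 0.031 and 8.8e-05.

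Muscle was marked by contractile genes. ACTA1 (skeletal actin, ENSSSCG00000010190) reached 60079 ± 15573 CPM in muscle, 11.1 ± 3.87 in fat and 21.4 ± 0.871 in liver. TPM1 and TPM2 (tropomyosins), TNNC2 (fast troponin C), MYL1 and MYL11 (myosin light chains), NEB (nebulin), ATP2A1 (calcium pump) and PYGM (muscle glycogen phosphorylase) followed, from 9403 ± 5448 CPM for PYGM to 16561 ± 10311 CPM for TPM1. MYH8, at 30476 ± 4344 CPM, belongs to a cluster of near-identical myosin heavy chain genes, so its level is uncertain. The log2 difference between muscle and fat for these 10 genes lay between 6.82 ± 0.66 for TPM1 (adjusted p 9.4e-04) and 12.46 ± 0.65 for ATP2A1 (adjusted p 1.6e-04).

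The fat-enriched genes of highest mean CPM included lipid droplet and lipid synthesis genes. FASN (fatty acid synthase) stood at 7333 ± 261 CPM in fat, 381 ± 218 in liver and 211 ± 213 in muscle. PLIN1 (perilipin 1, a lipid droplet coat protein, ENSSSCG00000001844) stood at 859 ± 335, 2.18 ± 1.44 and 57.3 ± 54.3 CPM in the same order. PLIN4, LIPE (hormone-sensitive lipase), ME1 (malic enzyme), RETSAT, ALDOC, BCAM, ANXA2 and THBS1 (thrombospondin 1) were also enriched. The log2 difference between fat and muscle lay between 2.58 ± 0.37 for PLIN4 (adjusted p 0.0052) and 5.25 ± 0.98 for FASN (adjusted p 0.015). Some calls ended although the direction stayed, with the log2 value of the full model in brackets: FASN in liver over fat without Korean native fat at -3.74 (-4.20), and in muscle over fat ANXA2 without Korean native fat at -2.14 or Korean native muscle at -1.92 (-2.71), ME1 likewise at -2.17 or -3.11 (-3.06), and THBS1 without the breed term at -2.87 (-2.75). FN1 did so in liver over fat with total counts at 1.38 or without Berkshire fat at 1.60 (2.41), and in liver over muscle without Korean native muscle at 2.23 (3.03).

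**Figure D1:**
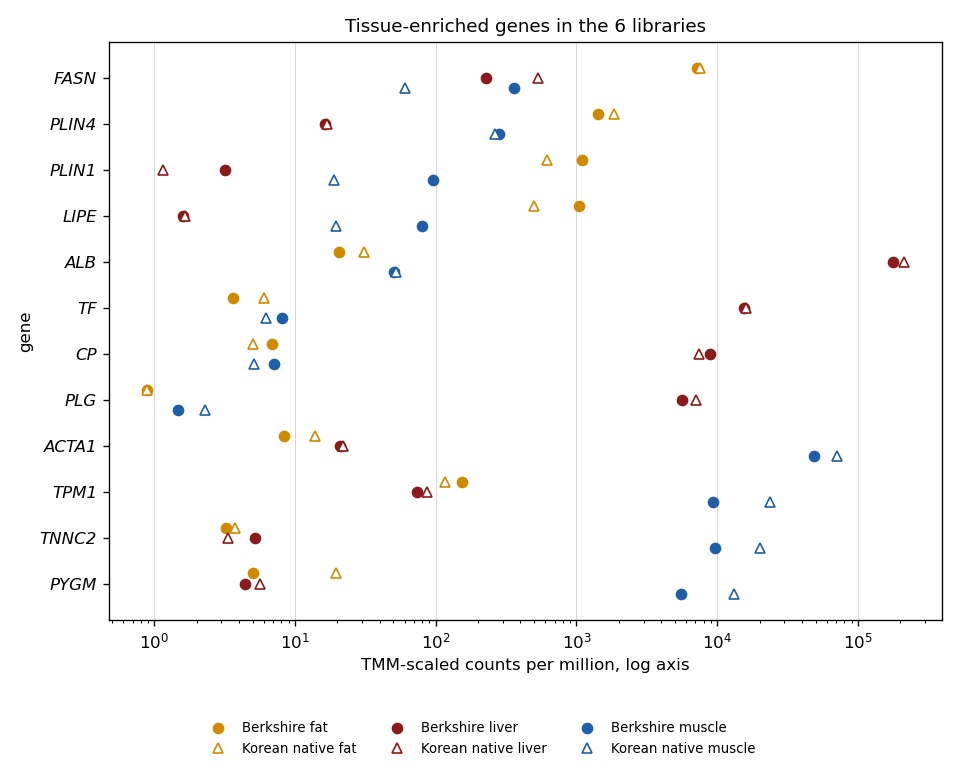
TMM-scaled CPM on a log axis for 12 tissue-enriched genes, 1 point per library, with colour for tissue and shape for breed. ALB lies at 194695 ± 25746 CPM in liver and ACTA1 at 60079 ± 15573 CPM in muscle (mean ± SD of the libraries of both breeds).

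Over all genes, 3959 changed between liver and fat (2100 higher and 1859 lower in liver), 2262 between muscle and fat (1374 higher and 888 lower in muscle) and 4964 between liver and muscle (2566 higher and 2398 lower in liver). Enriched genes numbered 1120 in liver, 625 in muscle and 215 in fat, and held 49.3% and 46.1% of the counts in Berkshire and Korean native liver, 34.7% and 42.8% in muscle and 6.50% and 6.08% in fat. Scaling by total counts moved the median gene to -0.94 between liver and fat and to -0.98 between muscle and fat on the log2 scale, from 0.06 and -0.05. Then 6955 and 6020 genes changed, 16.6% and 12.7% of them higher in liver or muscle against 53.0% and 60.7% with TMM factors, and 948 genes were enriched in fat. Without Korean native fat 2452 genes changed between liver and fat and 866 between muscle and fat, the latter being 1010 without Korean native muscle (74.5% higher in muscle) and 1475 without Berkshire fat. Fat-enriched genes numbered 117 without Korean native fat, 110 without Korean native muscle and 355 without Berkshire muscle.

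Gene lists fixed beforehand followed the tissues. All 19 tested hepatocyte markers rose in liver against fat, 19 also adjusted over the list alone, among them GC (vitamin D binding protein) at 5377 ± 1001 CPM and AMBP at 4522 ± 137 CPM in liver. All 21 urea cycle and amino acid genes rose (21 adjusted over the list alone), including CPS1, the entry enzyme of the urea cycle, at 3683 ± 920 CPM, MAT1A, HPD and TAT. Of 12 bile acid genes 11 rose (12 adjusted over the list alone), ABCB11 (bile salt export pump) standing at 544 ± 264 CPM in liver. Of 20 cholesterol synthesis genes 15 rose (18 adjusted over the list alone), with MSMO1 at 775 ± 646 CPM in liver. Complement and coagulation genes rose in 17 of 19 cases (18 adjusted over the list alone). Camera gave adjusted p of 6.1e-20, 1.3e-16, 2.8e-09, 4.1e-07 and 9.0e-15 for these 5 lists, but with an estimated correlation the adjusted p was 0.24, 0.24, 0.24, 0.54 and 0.37.

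In muscle, all 15 shared skeletal muscle genes, all 9 fast fibre genes and all 8 slow fibre genes rose against fat, with 15, 9 and 8 adjusted over the list alone. ENO3 (muscle enolase) was at 8429 ± 4624 CPM, and among slow fibre genes TNNT1 stood at 3224 ± 791 and TNNC1 at 2176 ± 877 CPM. Of 21 glycolysis genes 9 rose and 4 fell against fat (10 and 6 adjusted over the list alone), including LDHA (lactate dehydrogenase A) at 7325 ± 5580 CPM in muscle and 116 ± 84.2 in fat. Of 24 oxidative phosphorylation genes 9 rose and 1 fell (15 and 1 adjusted over the list alone), UQCRFS1 standing at 400 ± 133 CPM in muscle and 119 ± 5.02 in fat. Camera gave adjusted p of 2.2e-20, 1.8e-13, 1.2e-10, 0.016 and 1.5e-05 for these 5 lists, but with an estimated correlation the adjusted p was 0.24, 0.36, 0.24, 0.54 and 0.62.

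Fat stood apart from both other tissues by adipocyte and fatty acid synthesis genes, and from liver by matrix genes. Of 10 adipocyte markers 7 fell and 1 rose in liver against fat, and 8 fell in muscle against fat (7 and 8 fell adjusted over the list alone, where 1 also rose in muscle). The member that rose in liver was RBP4 (retinol binding protein 4, also secreted by liver), at 2416 ± 131 CPM in liver and 79.7 ± 60.0 in fat. Of 15 fatty acid synthesis genes 9 fell and 3 rose in liver, and 11 fell in muscle (9 and 12 fell adjusted over the list alone), ACACA (acetyl-CoA carboxylase) standing at 827 ± 286, 224 ± 23.1 and 48.5 ± 29.1 CPM in fat, liver and muscle. Of 24 matrix genes 20 fell and 1, FN1, rose in liver against fat (21 and 2 adjusted over the list alone), with COL3A1 (collagen III) at 10911 ± 2611 CPM in fat and 746 ± 103 in liver. In muscle against fat only 3 matrix genes fell and 21 did not pass (median log2 -0.73, camera adjusted p 0.0019, and 0.67 as adjusted p with an estimated correlation). Camera gave adjusted p of 3.1e-05, 0.034 and 4.4e-09 for the 3 lists in liver against fat, but with an estimated correlation the adjusted p was 0.43, 0.6 and 0.53. For adipocyte and fatty acid synthesis genes in muscle against fat it gave 8.0e-05 and 4.1e-07, and the adjusted p with an estimated correlation was 0.44 and 0.39. Triglyceride storage and lipolysis genes did not set fat apart. Of 12 such genes 4 rose and 3 fell in liver against fat, and 1 rose and 4 fell in muscle against fat (camera adjusted p 0.86 and 0.15).

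The breed comparison over all tissues asked which genes differed between the Korean native and Berkshire libraries over the 3 tissues. The 3 libraries of a breed are 3 tissues, possibly of 1 animal. A p-value here measures how steady a difference is across these libraries and is no evidence about the breeds as populations. PCK1 (phosphoenolpyruvate carboxykinase, a gluconeogenic enzyme, ENSSSCG00000007507) changed by -3.21 ± 0.33 (SE) on the log2 scale, lower in the Korean native libraries, with an edgeR adjusted p of 0.037. Its level in Berkshire and Korean native libraries was 78.3 and 6.90 CPM in fat, 2339 and 294 in liver and 6.04 and 0.692 in muscle. PCK1 was the only 1 of 15 called genes with a symbol. Of the other 14, 4 were higher and 10 lower in the Korean native libraries. ENSSSCG00000030790 had 87.3, 143 and 58.6 CPM in Berkshire fat, liver and muscle against 0.394, 0.331 and 0.231 CPM in the Korean native libraries. ENSSSCG00000016063 had 0 counts in all Korean native libraries, ENSSSCG00000030298 had 0 counts in all Berkshire libraries and 6.61, 24.2 and 15.7 CPM in Korean native fat, liver and muscle, and ENSSSCG00000029881 was also higher.

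Other named genes of smallest p did not pass. RER1 (log2 2.43 ± 0.30, adjusted p 0.063), TOPAZ1, PPP1R3C (a glycogen-targeting phosphatase subunit, 1.58 ± 0.24, adjusted p 0.13), SAL1 and UCHL1 had positive values. SPHK2 (-5.46 ± 0.72, adjusted p 0.078), ADAMTS4, FMO2 and TNC (tenascin C) had negative values. At an unadjusted p under 0.05 there were 1103 genes. Other splits of the libraries into 3 and 3 with 1 library of each tissue on each side gave 470, 416 and 557. The remaining splits gave 361 to 1656, but with tissue in the model they compare the libraries of 1 tissue only. DESeq2 called 94 genes, limma-voom 12 (6 higher and 6 lower), edgeR without a filter 87, and edgeR without the tissue term 0 (114 at an unadjusted p under 0.05). The count was 42 without Korean native fat, 46 without Berkshire fat, 72 without Berkshire liver, 83 without Korean native liver, 31 without Korean native muscle and 16 without Berkshire muscle, of which only 6 were among the 15, and PCK1 lost its call without Berkshire fat (log2 -3.02), Berkshire muscle (-3.23) or Korean native fat (-3.02) and without the tissue term (-3.01).

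Across lists, camera found the glucocorticoid and fasting response genes lower in the Korean native libraries (adjusted p 2.8e-08, median log2 -1.23), but with an estimated correlation the adjusted p was 0.71. Of 13 members, 1 passed over all genes and 7 adjusted over the list alone. Cholesterol synthesis genes were higher (adjusted p 8.0e-06, median 0.85) and matrix genes lower (adjusted p 7.7e-04, median -0.55). Oxidative phosphorylation (adjusted p 0.0016, median 0.33), glycolysis (0.0022, 0.46) and proteasome genes (0.0022, 0.36) were higher. In these last 5 lists 0 members passed in edgeR over all genes, and adjusted over the list alone 1 matrix gene and 0 of the others did. With an estimated correlation the adjusted p was 0.71, 0.71, 0.77, 0.77, 0.71 and 0.71 in that order. These values do not stand for each tissue: the list median within a tissue was 0.12 for cholesterol genes in muscle (11 of 19 higher, inside the central 95% of random lists), 0.33 for matrix genes and -0.26 for oxidative phosphorylation genes in fat, and -0.09 for glycolysis genes in liver.

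Among 8434 genes, 47 differed at least 2-fold in the same direction in fat, liver and muscle, 13 higher and 34 lower in the Korean native libraries. Turning the sign of fat, liver or muscle gave 6, 5 and 3 genes. RER1 was 4.08-fold, 6.51-fold and 5.03-fold higher in fat, liver and muscle, and PPP1R3C was 2.84-fold, 2.71-fold and 3.45-fold higher. NEDD4L (a ubiquitin ligase), TFRC (transferrin receptor), CXorf38 and C16orf87 followed, TFRC standing at 88.6 and 554 CPM in Berkshire and Korean native liver. PCK1, FMO2, RNF125, PDK4 (pyruvate dehydrogenase kinase 4, which limits glucose oxidation), THBS1 and HPGD were lower. PDK4 was 41.5-fold lower in fat (1060 and 25.2 CPM), 2.97-fold lower in liver (327 and 110 CPM) and 418-fold lower in muscle (3496 and 8.07 CPM). The count was 103 with a minimum of 1 CPM. As a choice made after the data were seen, pairs of tissues gave 81 genes in the same direction for fat and liver, 126 for fat and muscle and 159 for liver and muscle, against 21, 63 and 56 in opposite directions.

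In fat, 118 of 7994 genes were at least 4-fold apart, 50 higher and 68 lower in the Korean native library, with no replicate to test them. Among the largest ratios were those of SAL1 (a lipocalin, 1.66 and 1178 CPM in Berkshire and Korean native fat), KRT8, LIPG (endothelial lipase), S100A6, TIMD4, ANKEF1, SEMA3E, C9 (a terminal complement component) and MID1IP1. C9 stood at 8.23 and 77.8 CPM. Lower in Korean native fat were KERA, COL11A1, TNMD (tenomodulin), PDK4, COL11A2, PLCH2, MCTP2, COL6A5, PCK1 and WDR93. COL11A1 (a fibrillar collagen chain) stood at 99.1 and 1.18 CPM, and TNMD at 17.9 CPM and 0 counts. A minimum of 1 CPM in 1 library gave 306 genes, and 10 CPM in both libraries gave 34.

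Of the lists in fat, glucocorticoid and fasting response genes had a median log2 ratio of -1.45 (percentile 0 of random lists, 11 of 11 lower), with FBXO32 at 28.8 and 5.32 and PER1 at 288 and 85.7 CPM. Immediate early genes, which respond quickly to stimuli, had a median of -1.19 (percentile 0, 12 of 17 lower), including FOS at 827 and 172 and EGR1 at 718 and 227 CPM. Fatty acid synthesis genes had a median of 0.35 (percentile 99.2, 11 of 15 higher), SCD (stearoyl-CoA desaturase) standing at 5332 and 24349 CPM, and cholesterol genes a median of 0.66 (percentile 100, 17 of 20 higher), SQLE (squalene epoxidase) standing at 7.54 and 25.2 CPM. Glycolysis genes such as LDHA (56.3 and 175 CPM) had a median of 0.34. Macrophage markers (0.77, 12 of 13 higher, CD68 at 10.8 and 29.2 CPM), complement genes (0.98, C4A at 71.2 and 279 CPM) and matrix genes (0.33, FBN1 at 491 and 1262 CPM) also lay above the central 95% of random lists. Endothelial markers (-0.30, PECAM1 at 736 and 506 CPM), oxidative phosphorylation (-0.26) and triglyceride storage genes (-0.35, PNPLA2 at 561 and 354 CPM) lay below.

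In liver, 232 of 8357 genes were at least 4-fold apart, 114 higher and 118 lower in the Korean native library, again without a replicate. On the lower side, CYP2A19 had 1585 CPM in Berkshire liver and 0 counts in Korean native liver, CYP2E1 (an ethanol-metabolising cytochrome) 5397 and 7.13 CPM, CRP (C-reactive protein) 2682 and 7.46 CPM and FMO5 2351 and 12.9 CPM. MT3, MBL2 (mannose-binding lectin), ACAA2 (711 and 8.95 CPM), SULT1A3, LUZP2 and HSD17B11 (2936 and 68.4 CPM) followed. CYP2A19, CYP2E1, FMO5 and SULT1A3 belong to families of similar genes, and their levels are uncertain. The xenobiotic list as a whole had a median log2 ratio of -0.17 (percentile 9.29, 8 of 14 lower), inside the central 95% of random lists. Higher in Korean native liver were, among others, AADAT (0 counts and 203 CPM), MORC1, ADAD1, PNPLA3 (a lipid droplet protein, 0.400 and 42.3 CPM), GLYATL2, PAQR7, BBS12, CIMIP4 and ASB4. A minimum of 1 CPM in 1 library gave 474 genes, and 10 CPM in both libraries gave 95.

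Cholesterol synthesis genes in liver had a median log2 ratio of 1.59 (percentile 100, 19 of 20 higher), with HMGCS1 at 91.8 and 1556, SQLE at 38.0 and 387 and FDFT1 at 69.4 and 697 CPM in Berkshire and Korean native liver. Fatty acid synthesis genes had a median of 0.45 (FASN at 226 and 535 CPM) but were split, with 8 of 15 higher and 7 lower. Of these, 2 were at least 2-fold higher and 3 at least 2-fold lower. Bile acid genes had a median of 0.47 (10 of 12 higher, ABCB11 at 357 and 731 CPM). Apolipoprotein genes (0.40, APOA2 at 292 and 944 CPM) and oxidative phosphorylation genes (0.24) also lay above the central 95% of random lists. Below lay the glucocorticoid and fasting response (-0.89, percentile 0, 9 of 12 lower, IGFBP1 at 249 and 56.8 CPM), urea cycle and amino acid genes (-0.43, GPT2 at 155 and 11.8 CPM), acute phase genes (-0.32, LBP at 704 and 233 CPM), macrophage markers (-0.34) and matrix genes (-0.25).

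In muscle, 232 of 8252 genes were at least 4-fold apart, 96 higher and 136 lower in the Korean native library, and 54 of 267 were higher with total counts. PDK4 had the largest ratio on the lower side, followed by PADI2, MMP27, SGK2, COL2A1, POSTN (periostin, a matrix protein, 588 and 22.1 CPM), IGSF10, HPGD, ARID5B and ACTG2. Higher were MYBPH (myosin binding protein H, 19.0 and 1012 CPM), HOXC6 (0.915 and 52.4 CPM), ADORA1 (adenosine receptor A1, 17.8 and 647 CPM), SUSD1, NTMT2, HOXD9, SLC16A5, HOXA5, CIT and ACSM5. HOX genes mark position along the body axis. A minimum of 1 CPM in 1 library gave 601 genes, and 10 CPM in both libraries gave 91.

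All 24 matrix genes were lower in the Korean native muscle library, with a median log2 ratio of -1.51 (percentile 0), COL3A1 standing at 14585 and 2772 and COL1A2 at 4010 and 717 CPM. Adipocyte markers (-1.62, 8 of 10 lower, PLIN1 at 95.7 and 18.9 CPM), fatty acid synthesis genes (-0.79, SCD at 926 and 158 CPM), macrophage markers (-1.25, 12 of 12 lower, MRC1 at 44.8 and 13.8 CPM) and complement genes (-1.38, C4A at 72.1 and 20.5 CPM) were lower in that library as well. Fibroblast and smooth muscle markers (-0.54), cell cycle genes (-0.84, TOP2A at 24.3 and 7.61 CPM) and the glucocorticoid and fasting response (-1.26, 11 of 12 lower, FKBP5 at 267 and 39.0 CPM) lay below the central 95% of random lists too. Fast fibre genes had a median of 1.06 against 0.53 in matched random lists (8 of 9 higher, MYL11 at 6938 and 20428 CPM), glycolysis genes 0.82 (PKM at 3227 and 12264 CPM), oxidative phosphorylation genes 0.91 (24 of 24 higher, COX5A at 150 and 374 CPM) and proteasome genes 0.69 (16 of 16 higher). Random lists matched to the latter 3 had medians of 0.35, 0.26 and 0.15. Slow fibre genes had a median of 0.69 against 0.40 (6 of 8 higher) and lay inside the central 95% of random lists, as did shared skeletal muscle markers (0.27 against 0.53).

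**Figure D2:**
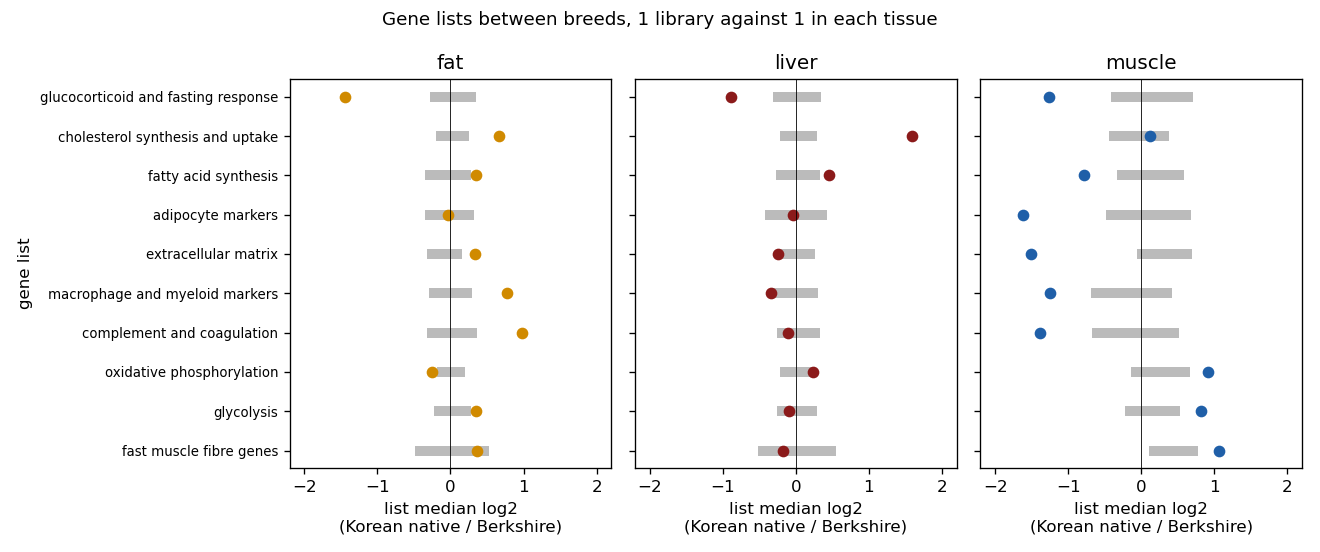
Median log2 ratio of Korean native over Berkshire CPM for 10 gene lists in each tissue (points), with the central 95% of medians of 10000 matched random lists (grey bars). The glucocorticoid and fasting response lies at -1.45, -0.89 and -1.26 in fat, liver and muscle, and cholesterol genes lie at 0.66, 1.59 and 0.12.

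**Figure D3:**
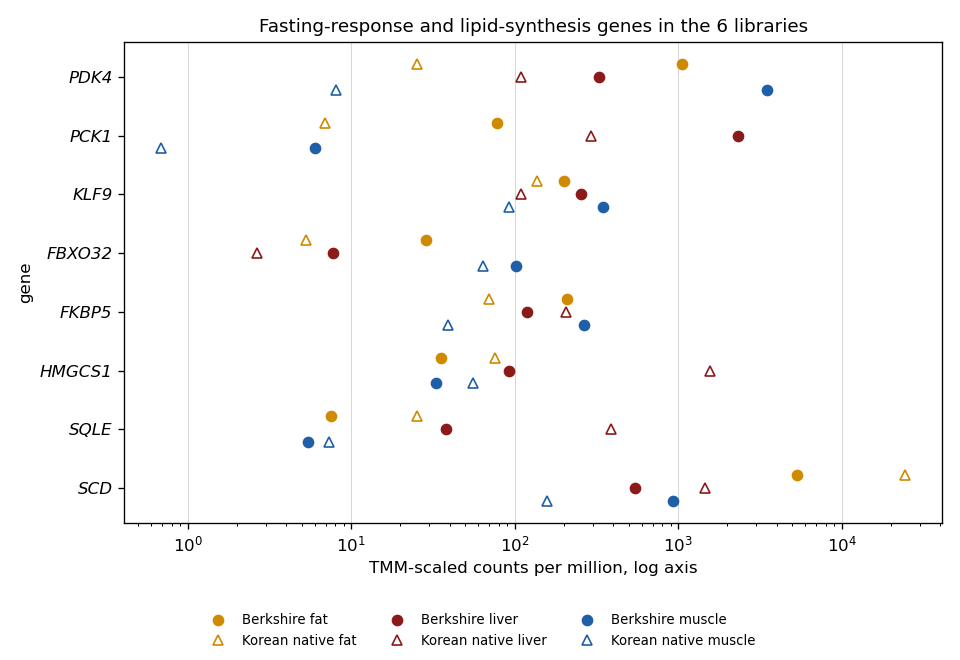
TMM-scaled CPM on a log axis for 8 genes of the fasting response and of lipid synthesis, 1 point per library, with colour for tissue and shape for breed. PDK4 lies at 1060 and 25.2 CPM in Berkshire and Korean native fat and at 3496 and 8.07 CPM in muscle.

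In all, 41 of 103 pairs of list and tissue lay outside the central 95% of random lists. With median-of-ratios factors and total counts, 43 and 42 did so. About 5.2 would by chance if the genes of a list varied independently of each other. The inter-gene correlation estimated by camera ranged from -0.04 for urea cycle genes to 0.97 for oxidative phosphorylation genes. The gap between 41 and 5.2 is therefore no measure of an excess. The 41 include mitochondrially encoded genes in fat (median 0.32) and liver (0.42), which say little because few genes are as abundant and random lists repeat them (random medians -0.39 and 0.27). The same limit holds for acute phase genes in liver and fast fibre genes in muscle, whose random lists had medians of 0.27 and 0.53. Across the 8434 genes compared in every tissue, the breed ratio correlated between fat and liver (r = 0.23, rho = 0.133), fat and muscle (r = 0.16, rho = 0.0385) and liver and muscle (r = 0.226, rho = 0.198). These correlations are across genes, which are not independent replicates.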

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

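All tests weighed here were chosen after the result was seen.

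Between 45.91% and 52.5% of the listed reads of a library fell in no annotated gene: 52.5% in Berkshire fat, 45.91% in Berkshire liver, 50.28% in Berkshire muscle, 52.04% in Korean native fat, 47.83% in Korean native liver and 49.79% in Korean native muscle. These reads were not analysed here.

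Some lists pointed in opposite directions between tissues, and these differences were not tested. Median log2 ratios of Korean native over Berkshire in fat, liver and muscle were 0.35, 0.45 and -0.79 for fatty acid synthesis, -0.26, 0.24 and 0.91 for oxidative phosphorylation, 0.33, -0.25 and -1.51 for matrix genes and 0.77, -0.34 and -1.25 for macrophage markers. In liver the fatty acid synthesis list was split, with 8 members higher and 7 lower. Complement and coagulation genes had 0.98 in fat and -1.38 in muscle. Interferon-stimulated genes had 0.31 in liver, where MX1 stood at 57.4 and 151 CPM, and -0.49 in muscle, where IFI44L stood at 47.2 and 19.8 CPM.

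Single genes did so too, again not tested. HOXA5 had a log2 ratio of 3.21 in muscle and -1.15 in fat, C9 had 3.20 in fat and -1.03 in muscle, and TIMD4 had 3.39 in fat and -1.21 in liver. SLC16A5 had 3.38 in muscle and -3.12 in liver, SULT1A3 had -5.91 in liver and 1.13 in fat, and SGK2 had -5.27 in muscle and 2.63 in liver.

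Glucocorticoid and fasting response genes were lower in all Korean native libraries. A scaling factor moves all genes of a library alike, so it does not change where a list lies among matched random lists. The list median lay below their lower limit in every tissue (nearest difference -0.58 on the log2 scale). The list was picked on that ground, so this is no separate test of scaling. Without PCK1 and PDK4, a choice made after the data were seen, the medians were -1.29, -0.57 and -1.23 in fat, liver and muscle, at percentiles 0, 0.17 and 0 of random lists, so these 2 genes alone do not account for it. A fasted Berkshire source could have such genes raised in all tissues, but the fatty acid oxidation list in liver lay at percentile 92.1, inside the central 95%, and decides nothing. Feeding, handling and breed cannot be told apart, because the labels give no feeding or slaughter details.

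Adipocyte, matrix and macrophage genes were higher in the Berkshire muscle library. Fat tissue carried in that library is a candidate source of the adipocyte signal. The share of Berkshire fat needed was the Berkshire minus the Korean native muscle CPM, over the Berkshire fat CPM. It takes Korean native muscle as free of carried fat and, being TMM-scaled, is no share of library RNA. The share had a median of 5.97% for 10 adipocyte markers (quartiles 2.05% and 6.93%) and 6.58% for 15 fatty acid synthesis genes. GPD1 (-522%) and CFD (-15.1%) went against the other 8 adipocyte markers. Matrix genes would need 57.7% (quartiles 43.8% and 85.2%), POSTN 555% and macrophage markers 41.3% (quartiles 26.7% and 71.2%). This argues against fat of the composition of the Berkshire fat library as the source of the matrix genes. Fat tissue richer in matrix was not measured and stays open. The adipocyte, matrix and macrophage list medians lay below the lower limit of matched random lists (nearest difference -0.57 on the log2 scale). Scaling moves lists and random lists alike, and these lists were picked on that ground, so this is no separate test of scaling. Muscle taken from another body position stays open. HOX genes with at least 1 CPM in any of the 6 libraries were taken, without those already named. The 8 genes of groups 5 and above had a mean log2 ratio of 1.91 and the 8 of groups 1 to 4 had -0.27. The two-sided exact permutation p was 0.052 across genes, which lie in clusters and are not independent. That minimum also looked at the muscle libraries, and HOXD1, of groups 1 to 4, passed it only through Korean native muscle (7.15 CPM). This p therefore decides nothing. The permutation p of 0.0040 over all HOX genes and of 0.048 without the named ones were found first, with a minimum of 1 CPM in muscle. They are void because that minimum looked at the libraries compared. Among the genes of groups 5 and above, HOXA10 and HOXA11 had 0 counts in both muscle libraries, so their log2 ratios of 0 hold no information. Position and breed are confounded in these 2 libraries.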

How the results depend on the processing

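No paired analysis was possible because the labels name no animals, so libraries were matched only by breed and tissue in the additive model. With a library left out, the lone library of a tissue was assumed to vary like the others. Leaving out either library of a tissue leaves the breed difference to the same libraries of the other tissues. For breeds, these omissions are therefore not separate checks. Of 14 counts under all alternatives, 87 values lay within 1.5 times the reported count and 30 did not. For 318 results on single genes and lists, 1541 values kept their side of the threshold or their counting interval, 13 lost a call, 30 gained 1 and 64 left their interval, 56 of these with total counts. None of the 318 changed sign, whereas with total counts the medians of some lists inside the random band did (cholesterol genes in muscle from 0.12 to -0.18, hepatocyte markers in fat from 0.58 to -0.04). With total counts 6955 genes changed between liver and fat, 6020 between muscle and fat, and 948 were enriched in fat; the breed median moved from 0.02 to -0.12. Breeds over tissues gave 94 genes with DESeq2, 87 without a filter and 0 without the tissue term. At least 4-fold apart were 306, 474 and 601 genes in fat, liver and muscle with 1 CPM in 1 library, and 34, 95 and 91 with 10 CPM in both. Shared directions gave 103 genes with 1 CPM, and, chosen after seeing the data, 81, 126 and 159 for fat and liver, fat and muscle, and liver and muscle. With an estimated correlation 0 of 64 calls of lists between tissues and 0 of 15 between breeds were kept. The 2 residual degrees of freedom used there raise the p at any correlation, so these losses are not by themselves a sign of correlated genes. Leaving out 1 library gave 2452 to 4823 genes between liver and fat, 866 to 2652 between muscle and fat, 16 to 83 between breeds and 110 to 355 enriched in fat. The cause was not tested. Depth limits genes near 3 counts, and the self-test recovered few 2-fold changes (3 of 57 between tissues and 2 of 65 between breeds). Unchanged genes made up a larger share of its calls than 0.05 in both comparisons.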

Other observations

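The tests of the 15 called genes below were chosen after the result was seen.

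Neural and Schwann cell markers, which mark nerve-associated cells, were higher in the Korean native fat library (8 of 8 higher, median log2 ratio 1.43, percentile 100). CDH19 stood at 2.35 and 6.90 CPM in Berkshire and Korean native fat. In muscle the list median was -0.81 (percentile 3.38). Heat shock and chaperone genes were lower in Korean native fat (-0.31, 17 of 19 lower) and liver (-0.34, 14 of 18 lower), with DNAJB1 at 54.2 and 21.2 CPM in fat and BAG3 at 290 and 151 CPM in liver. In muscle the median was 0.15 against 0.26 in matched random lists, inside their central 95%. HSPA1L, at 1361 and 299 CPM in fat, has near-identical neighbours and its level is uncertain.

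Circadian clock genes had a lower median in Korean native liver (-0.35, percentile 1.32, 8 of 14 lower), with BMAL1 at 10.4 and 2.65, CRY1 at 21.2 and 6.13 and PER1 at 187 and 83.8 CPM. The list median was -0.19 in fat (8 of 14 lower) and -0.42 in muscle (9 of 14 lower), both inside the central 95% of random lists. The time of sampling is not given in the sources used here. T cell markers rose in liver against muscle in 11 of 13 cases (13 adjusted over the list alone), CD4 standing at 25.1 ± 6.93 CPM in liver and 1.76 ± 2.17 in muscle (mean ± SD, both breeds). Camera gave an adjusted p of 1.5e-05, and with an estimated correlation the adjusted p was 0.38.

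Of the 15 genes called between breeds over tissues, 14 lacked a symbol, against 4706 of 13810 tested genes (34.1%; odds ratio 27.2, two-sided Fisher's exact p = 2.9e-06). Under 1 CPM in all Korean native libraries were 7 of them, and in all Berkshire libraries 2. Gene models that match the DNA of 1 breed only are a candidate explanation, but deletion, sequence divergence, gene copies and a difference in expression cannot be told apart from counts. A missing symbol is no mark of such a gene model, because established genes such as ADIPOQ, CKM and LPL also matched no ID. Of the 10 splits of the 6 libraries into 3 and 3, 1 gave as many genes, the real split with 15, and the highest of the others gave 0. These splits are too few for a share under 0.05. Those with both libraries of a tissue on the same side compare the libraries of 1 other tissue only, so fewer still are like the real split.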
